A study of Homo sapiens with 2 samples.

How the data were processed

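The deposited counts are UMI counts per gene and barcode for 2 libraries, made by the authors before deposit. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.1 against hg38 and later steps used Seurat. The annotation release and the rule by which the submitters chose barcodes are not given in the sources used here. The barcodes reached down to 718 and 509 UMIs, and each listed gene was seen in at least 5 cells of its library (19399 and 18963 genes). Clustering or normalisation by the submitters was not used here. Per the labels, library 1 is batch 1 and library 2 is batch 2. Whether the libraries are separate cultures is not stated. The p-values below therefore measure only the spread between 2 libraries, with library and batch confounded, and intervals of counts and shares cover counting error only.

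Y-linked genes and XIST were left out before any analysis. Cells were barcodes with at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs; a limit of 5% was an alternative. The planned analyses were fixed before the data were examined. After the barcodes proved to fall into a shallow and a deep group, barcodes with at least 10000 UMIs (deep) and with 10000 to 80000 UMIs were added as alternatives. Barcodes present in both libraries (15) were kept as separate cells. Doublets were not removed: Scrublet, run through scanpy, called 1 cell in replicate 1 and 0 in replicate 2, which was taken as a failure of the method, and its calls were not used. Run on deep barcodes it called 12 in replicate 1 (median 81648 UMIs) and 2 in replicate 2 (median 61008.5 UMIs), which were not removed either. A doublet can place transcripts of different cells in 1 barcode and so raise both classes of a contrast.

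Levels are sums of UMIs over the cells of a library divided by all UMIs of these cells, as counts per 1e+06 UMIs (CPM), with exact Poisson intervals. The gene lists (18) and marker lists were written from general knowledge before the files were seen: inflammatory secreted factors, SASP growth factors and proteases, NF-kB, interferon-stimulated, complement and acute phase, antigen presentation, DNA replication, mitosis, arrest and quiescence, p53 targets, collagen and matrix, contractile, YAP targets, immediate early and dissociation stress, cholesterol synthesis, lysosome and autophagy, hypoxia and glycolysis, and mitochondrially encoded genes. Of the lists, 32 of 34 interferon-stimulated, 15 of 18 complement and 13 of 14 antigen presentation genes were in either library, and the other gene lists were complete. Of the marker lists, 5 of 10 epithelial, 7 of 8 endothelial, 6 of 10 immune, 3 of 6 mesothelial and 3 of 6 erythroid genes were in either library. Named genes are the list members with the highest level, genes fixed beforehand, and the 10 largest changes each way among passing genes with at least 20 CPM. For library ratios they are the 5 largest each way at 100 CPM. CSF2, CXCL10 and CCL7 were named for their spread after their values were seen. Counts of reads that match near-identical gene copies depend on the upstream counting, which leaves the levels of FTH1, MT2A, IFITM2 and IFITM3 uncertain. Values of some single list members are not reported.

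Spread was the number of cells with a UMI over the number expected from a Poisson model with the depth of each cell, for genes with at least 10 CPM. Co-variation was the mean pairwise correlation of Pearson residuals (overdispersion parameter 100) in cells thinned to 1000 UMIs (deep barcodes: 19500). Both were ranked among 10000 random lists drawn from the 100 genes nearest in expression to each member. A cell was counted as carrying mitosis transcripts with UMIs from at least 3 mitosis genes after thinning. For the contrasts cells were scored on thinned UMIs, the highest and lowest 25% per library (or 3 or more mitosis genes against none) were summed without thinning, and the scored genes were left out of the test. Sums were fitted with edgeR's quasi-likelihood test with TMM scaling, its default low-count filter and a replicate block. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The SE given for a fold change is its absolute size over the square root of the test's F statistic. It restates the test and can lie below the counting error where a class holds few UMIs. Lists were called with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. None of the calls printed in the report held at 0.05 with the estimated correlation. In that form camera is limited by the residual degrees of freedom, which so few sums hardly leave, so it could hardly reach 0.05 whatever the change. For SASP genes in the inflammatory contrast camera's p went from 1.901e-12 to 0.0795, although the estimated correlation of -0.0345 lay below the preset one. Those p-values are therefore no evidence that a list is unchanged. Contrasts of 20 random scores show how many genes any score finds. Both classes of a contrast come from the same libraries and are chosen by expression, so the adjusted p-values describe the chosen cells and not a treatment.

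The methods were tested on simulated data. For the contrasts 200 genes were changed, and both classes were drawn from the means of the low class without choosing cells by a score. The simulation therefore checks the fit and does not measure false calls where classes are chosen by expression. For the inflammatory contrast 89.6% of genes changed 2-fold were recovered with 3.75% false calls, for the p53 contrast 78.7% with 3.27%, and for the mitosis contrast 66% with 6.25%. A list simulated with even spread lay at percentile 15.54 for spread and 58.95 for co-variation, a list with uneven spread at percentile 0 and a list with a shared factor at percentile 100. Alternatives were other depth and mitochondrial limits, thinned sums, the top and bottom 10%, a sum score, 2 or 5 mitosis genes, no TMM, no low-count filter, no replicate block, DESeq2, leaving a replicate out, log-scale residuals and other cluster resolutions. Leaving a replicate out gives fold changes without a test. Clusters were made with scanpy by the Leiden method at resolution 0.5; resolutions 0.3 and 1.0 gave 6 and 11 clusters. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.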

Results

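LF1 cells, an established line of human lung fibroblasts, were profiled by droplet single-cell RNA sequencing after entry into quiescence, the reversible arrest of cells that remain able to divide. The cells had been held at 100% confluency for 3 days, which arrests fibroblasts by contact inhibition, and then kept for 2 days in medium with 0.01% fetal bovine serum in place of 10%. Per the labels, the culture of both libraries was at 3% oxygen and 5% carbon dioxide. The 2 libraries form 1 group. The series title addresses whether quiescent cells carry an inflammatory transcript program resembling that of senescent cells. Proliferating and senescent cells are not analysed here, so the comparisons are between cells within the quiescent libraries. Replicate 1 held 8100 barcodes with 129487967 unique molecular identifiers (UMIs), and replicate 2 held 6619 barcodes with 125523338 UMIs. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept as cells, which left 5202 cells (median 13967.5 UMIs and 3346 genes) in replicate 1 and 3662 cells (median 28135.5 UMIs and 4589.5 genes) in replicate 2. The barcodes fell into a shallow and a deep group, and barcodes with at least 10000 UMIs are called deep here (2696 and 2249 barcodes). The deep barcodes held 91.5% and 94.0% of all UMIs.

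**Figure D1:**
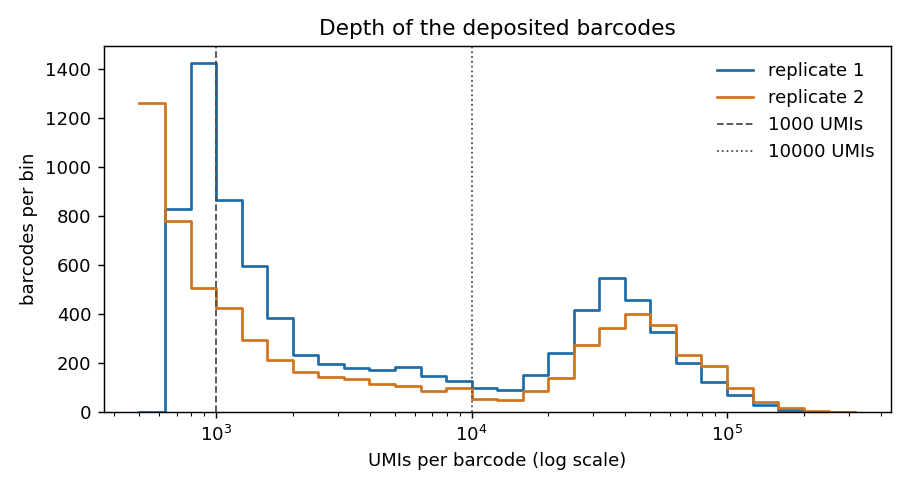
Barcodes per bin against UMIs per barcode (log scale) in the deposited counts of both replicates, with lines at 1000 and 10000 UMIs. Both libraries have many barcodes around or below 1000 UMIs and a peak between 10000 and 100000 UMIs; 2696 and 2249 barcodes above 10000 UMIs are called deep.

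Transcripts of inflammatory secreted factors were abundant in the quiescent cells. CXCL8, the neutrophil chemoattractant interleukin-8, reached 12446 ± 2433 CPM (counts per 1e+06 UMIs of the library; mean ± SD, n = 2) and was the fourth most abundant transcript, after FTH1, MALAT1 and MT2A. The chemokines CXCL3 and CXCL1 stood at 3128 ± 371 and 2746 ± 33.4 CPM (SD, n = 2), and the cytokine IL6 at 2248 ± 584 CPM (SD, n = 2). IL1B and IL1A, the genes of interleukin-1 beta and alpha, were at 833 ± 21.5 and 98.1 ± 25.2 CPM (SD, n = 2), and the monocyte chemoattractant CCL2 at 511 ± 75.0 CPM (SD, n = 2). All 29 genes of the list were present in both libraries, 24 of them at 1 CPM or more in both, and together they made up 28126 ± 3948 CPM (SD, n = 2). For CXCL8 in replicate 1 the exact Poisson 95% interval ran from 10708 to 10744 CPM around 10726, so counting error was small beside the difference from the 14167 CPM of replicate 2. In the deep barcodes CXCL8 was at 12610 ± 2442 CPM (SD, n = 2).

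**Figure D2:**
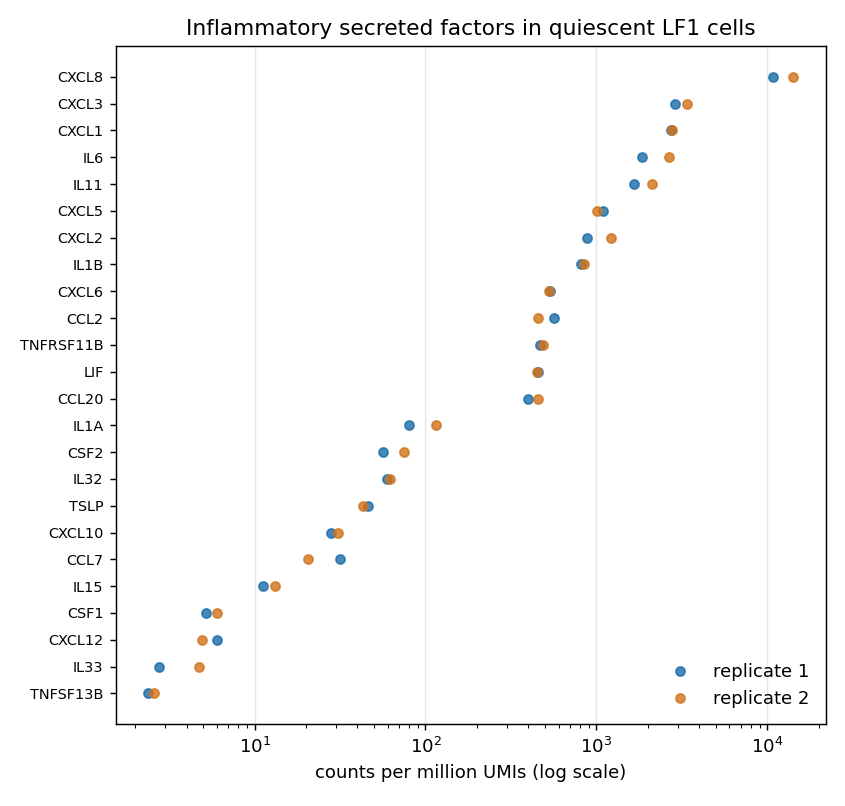
CPM (log scale) of the inflammatory secreted factors with at least 1 CPM in both libraries, 1 point per replicate. CXCL8 lies highest at 10726 and 14167 CPM, and IL33 and TNFSF13B lie lowest.

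Growth factors and proteases known from the senescence-associated secretory phenotype (SASP) summed to 24459 ± 1416 CPM (SD, n = 2) over 29 genes. The protease inhibitor TIMP1 was at 4790 ± 61.0 CPM, the stress cytokine GDF15 at 3639 ± 643, the insulin-like growth factor binding protein IGFBP5 at 2718 ± 17.2 and the plasminogen activator PLAT at 1983 ± 43.4 (SD, n = 2). Targets and regulators of NF-kB, the transcription factor family behind much cytokine expression, summed to 9814 ± 875 CPM (SD, n = 2). Among them the survival gene IER3 was at 4816 ± 505 CPM, the superoxide dismutase SOD2 at 1860 ± 32.7, the prostaglandin synthase PTGS2 at 1473 ± 139 and TNFAIP6 at 466 ± 85.4 (SD, n = 2). Interferon-stimulated genes summed to 989 ± 11.7 CPM (SD, n = 2), led by the antiviral membrane proteins IFITM3 and IFITM2 at 389 ± 7.44 and 253 ± 0.432 CPM. Complement and acute phase genes summed to 1006 ± 54.4 CPM (SD, n = 2), led by the complement inhibitor CD59 at 274 ± 3.71 and the pentraxin PTX3 at 199 ± 55.2. Antigen presentation genes summed to 3444 ± 164 CPM (SD, n = 2), of which B2M gave 1687 ± 50.9.

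Cell cycle transcripts were scarce. The mitosis list summed to 358 ± 31.2 CPM (SD, n = 2) over 32 genes, with the proliferation marker MKI67 at 14.4 ± 1.496, CENPF at 31.8 ± 1.62 and TOP2A at 25.2 ± 0.818. The DNA replication list summed to 347 ± 2.40 CPM (SD, n = 2), with DUT at 77.6 ± 3.72 and PCNA at 31.8 ± 0.482. The nuclear lamina gene LMNB1, which senescent cells are known to lose, was at 3.12 ± 0.088 CPM (SD, n = 2). The cyclin-dependent kinase inhibitors CDKN1A (p21), CDKN2A (p16) and CDKN2B (p15) were at 266 ± 32.2, 32.9 ± 3.68 and 9.29 ± 0.385 CPM (SD, n = 2). The arrest and quiescence list summed to 2447 ± 20.9 CPM, with the antiproliferative gene BTG1 at 876 ± 18.5, HMGB1 at 493 ± 40.8 and CCND1 at 346 ± 4.99 (SD, n = 2). This list is mixed, since it also holds LMNB1 and the cyclin gene CCND1, and its genes are called arrest genes below for short. Targets of p53, the checkpoint transcription factor, summed to 2042 ± 129 CPM, with RPS27L at 657 ± 13.1 and the apoptosis gene BAX at 203 ± 4.57 (SD, n = 2).

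Structural and metabolic genes gave the remaining lists. Collagen and matrix genes summed to 6275 ± 82.3 CPM (SD, n = 2), with COL6A2 at 780 ± 35.0, the proteoglycan DCN at 716 ± 34.1 and FN1 at 601 ± 25.6. Contractile genes summed to 3047 ± 93.5 CPM, led by the tropomyosins TPM2 (1370 ± 26.6) and TPM4 (518 ± 22.1), and YAP targets to 1199 ± 46.9 CPM, led by CCN2 (558 ± 30.3; SD, n = 2). Immediate early and dissociation stress genes, which respond to serum and to trypsin, summed to 3375 ± 180 CPM, with JUN at 545 ± 19.2 and DUSP1 at 417 ± 132 (SD, n = 2). Cholesterol synthesis genes summed to 321 ± 19.8 CPM (FDPS 46.8 ± 0.986), lysosome and autophagy genes to 2476 ± 138 (SQSTM1 762 ± 60.2), hypoxia and glycolysis genes to 5215 ± 93.6 (LDHA 1075 ± 15.3) and mitochondrially encoded genes to 24885 ± 2106 (MT-CO1 7057 ± 78.1; SD, n = 2).

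All 10 fibroblast markers were present, from VIM at 2969 ± 138 CPM and DCN at 716 ± 34.1 down to THY1 at 76.9 ± 7.43 and PDGFRB at 24.8 ± 3.16 (SD, n = 2). Markers of other cell types were lower than the lowest of these. The epithelial marker EPCAM was at 0.175 ± 0.008 CPM, the endothelial PECAM1 at 0.264 ± 0.044, the leukocyte PTPRC at 0.045 ± 0.018 and the mesothelial MSLN at 0.138 ± 0.009 (SD, n = 2). The highest in each of these groups were KRT19 (6.09 ± 2.07), EGFL7 (10.0 ± 0.001), CD68 (13.7 ± 1.47) and CALB2 (0.305 ± 0.001), all below 14.376 CPM, the level of MKI67. Of the pericyte or smooth muscle markers NOTCH3 was highest at 9.44 ± 0.159 CPM, and of the erythroid markers HBG2 at 2.94 ± 3.16 CPM (SD, n = 2).

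The libraries differed little from each other. Over 12064 genes with at least 1 CPM in both, log2 CPM correlated at r = 0.996 across genes, which are not independent replicates, and 7 genes differed by more than 2-fold. Among genes with at least 100 CPM, the phosphatase gene DUSP1 (log2 ratio 0.66), GEM (0.65), the stress transcription factor DDIT3 (0.64), NR4A2 (0.61) and CKS2 (0.61) were highest in replicate 2 relative to replicate 1. MT-ND3 (-0.57), the growth factor receptor gene PDGFRA (-0.54), IL24 (-0.38), ATP5ME (-0.38) and TRPA1 (-0.38) were lowest. By list, mitochondrially encoded genes had a median log2 ratio of -0.26, with 13 of 13 lower in replicate 2, at percentile 0 of 10000 expression-matched random lists. Mitosis genes (median 0.18, 27 of 32 higher, percentile 100), NF-kB genes (0.17, 15 of 16 higher, percentile 100) and inflammatory factors (0.12, 17 of 24 higher, percentile 99.99) were higher in replicate 2. Each batch label holds 1 library, so library and batch cannot be told apart, and no test was made.

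A small share of cells carried mitosis transcripts. After each cell was thinned to 1000 UMIs, UMIs from 3 or more mitosis genes were present in 132 of 5202 cells of replicate 1 (2.54%, exact Clopper-Pearson 95% interval 2.13 to 3.00) and in 104 of 3662 cells of replicate 2 (2.84%, interval 2.33 to 3.43), a mean of 2.69 ± 0.214% (SD, n = 2). MKI67 was seen in 2.46% and 3.22% of cells where 23.1% and 33.1% would be seen if its UMIs followed depth alone. Without thinning the share was 12.7% and 17.8%, since deeper cells show more genes. The share depends on the depth to which cells are thinned. In deep barcodes thinned to 19500 UMIs it was 6.01% (146 of 2431) and 6.77% (142 of 2097), with 265 and 152 shallower barcodes left out. Over all barcodes thinned to 1000 UMIs, the share was 2.33% and 4.07% at 1000 to 2000 UMIs and 5.12% and 3.61% at 2000 to 5000. It was 0.603% and 0.435% at 20000 to 50000 UMIs, and 3.28% and 3.59% from 50000 up. At equal depth, deep barcodes were thus not richer throughout. No UMI of any mitosis gene was left in 4504 and 3238 thinned cells.

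Inflammatory transcripts were spread over cells less evenly than other transcripts of similar abundance. For 20 inflammatory genes with at least 10 CPM in both libraries, the median log2 ratio of observed to expected cells with a UMI was -0.40 in replicate 1 and -0.39 in replicate 2, at percentile 0 of random lists, whose median was -0.057. CSF2, the growth factor GM-CSF, was seen in 13.0% and 16.6% of cells against 49.9% and 64.0% expected from depth, and the tenth of cells with most of its UMIs held 97.6 ± 0.33% of them (SD, n = 2). CXCL10, CCL7 and IL1A had observed to expected ratios of 0.270 ± 0.049, 0.352 ± 0.045 and 0.496 ± 0.006 (SD, n = 2). IL6 was seen in 87.8% and 89.5% of cells, a ratio of 0.904 ± 0.002, and CXCL8 in 99.9% and 99.9% of cells, a ratio of 0.999 ± 0.000 (SD, n = 2). Over all lists the lowest ratios at full depth were those of the mitosis genes ASPM (0.10 ± 0.022), MKI67 (0.102 ± 0.007), TOP2A (0.136 ± 0.006), UBE2C (0.138 ± 0.016) and TPX2 (0.172 ± 0.021), and the highest those of TPM4 (1.02 ± 0.006), CXCL8 and SREBF2 (0.998 ± 0.012; SD, n = 2).

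A CXCL8 UMI was not limited to barcodes with the depth of a cell, so the share of cells with a UMI is not read as a share of expressing cells. Barcodes under 1000 UMIs (2250 and 2546) held CXCL8 at 10430 and 12035 CPM, and 99.8% and 99.8% of them had a CXCL8 UMI, at a median of 8 and 7 CXCL8 UMIs. Of the deep barcodes, whose median was 267 and 435 CXCL8 UMIs, 86.1% and 86.2% lay above the 99th percentile of these shallow barcodes. The same share was 64.0% and 73.3% for IL6, 61.5% and 65.9% for IL1B, 49.0% and 45.7% for CCL2, and 8.42% and 11.9% for CSF2. These shares compare raw UMI counts, which greater depth alone raises, so they mark no cells above the level of free RNA. Relative to depth, fewer deep barcodes lay above 1.5 times the CPM of shallow ones. They were 27.0% and 31.9% for CXCL8, 22.1% and 28.2% for IL6 and 24.2% and 25.8% for IL1B. For CCL2 they were 24.8% and 23.25%, and for CSF2 4.97% and 6.18%. CXCL8 ranged in the deep barcodes of replicate 1 from 418 CPM at the 10th percentile to 31106 CPM at the 90th, around a median of 7050.

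Among other lists, mitosis (median log2 ratios -2.34 and -2.42), complement and acute phase (-0.49 and -0.49), collagen and matrix (-0.35 and -0.38), arrest and quiescence (-0.29 and -0.27), YAP targets (-0.28 and -0.28), SASP (-0.26 and -0.25), mitochondrially encoded (-0.25 and -0.21), immediate early (-0.24 and -0.20), contractile (-0.21 and -0.23), NF-kB (-0.19 and -0.22), p53 targets (-0.19 and -0.23) and DNA replication genes (-0.21 and -0.25) lay below percentile 1 in both libraries. Interferon-stimulated and lysosomal genes lay between percentile 1.31 and 2.87. Antigen presentation, cholesterol synthesis and hypoxia genes, between percentile 5.34 and 36.41, were not set apart from random lists. When every cell was thinned to 1000 UMIs, p53 target, interferon-stimulated and lysosomal genes were not set apart either (percentiles 5.5 to 83.64), and arrest genes lay at percentiles 6.13 and 1.9. Thinning also brought the medians nearer to 0 for mitosis (-0.25 and -0.38), complement (-0.061 and -0.092), collagen (-0.17 and -0.18) and YAP target genes (-0.059 and -0.058), so that mitosis genes no longer lay below the inflammatory list (-0.38 and -0.42). Medians were also nearer to 0 in deep barcodes for SASP (-0.11 and -0.093), NF-kB (-0.13 and -0.11) and immediate early genes (-0.12 and -0.14), and mitochondrially encoded genes (-0.011 and -0.018, percentiles 5.44 and 1.29) and lysosomal genes (percentiles 30.18 and 37.04) were not set apart there in both libraries. The inflammatory list stayed at percentile 0 in both of these settings.

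Inflammatory genes varied together from cell to cell. The mean pairwise correlation of their depth-adjusted residuals was 0.077 in replicate 1 and 0.083 in replicate 2 over 19 genes, above all 10000 random lists of matched expression (percentile 100 in both; cells are not replicates, and each library gives 1 value). In deep barcodes, where 25 genes could be used, the closest pairs were IL6 with CXCL8 (mean r = 0.57), CXCL8 with CXCL3 (0.56) and CXCL2 with CXCL3 (0.56), while IL11, an interleukin-6 family cytokine, ran against CCL2 (-0.14). In cells thinned to 1000 UMIs, mitochondrially encoded (0.37 and 0.35), mitosis (0.22 and 0.24), contractile (0.15 and 0.15) and collagen genes (0.094 and 0.11) had higher mean correlations than the inflammatory list. In deep barcodes the inflammatory list (0.061 and 0.059) also lay below DNA replication (0.16 and 0.19), p53 target (0.15 and 0.16), NF-kB (0.14 and 0.15), hypoxia (0.13 and 0.16), complement (0.083 and 0.067) and antigen presentation genes (0.075 and 0.078). NF-kB (0.042 and 0.054), SASP (0.032 and 0.037), antigen presentation (0.047 and 0.041), DNA replication, immediate early, hypoxia, complement, p53 target, lysosomal and YAP target genes also lay above percentile 99 in both libraries at 1000 UMIs. Interferon-stimulated, arrest and cholesterol synthesis genes were not set apart from random lists at 1000 UMIs, but in deep barcodes interferon-stimulated genes lay at percentile 100 (0.025 and 0.027) and arrest genes at 98.36 and 98.44.

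The inflammatory score of a cell followed that of NF-kB genes (r = 0.45 and 0.50 across the cells of replicates 1 and 2) and of SASP genes (0.36 and 0.36). It ran against the scores of contractile genes (-0.32 and -0.34), hypoxia and glycolysis genes (-0.19 and -0.21), mitosis genes (-0.14 and -0.13) and collagen genes (-0.13 and -0.10). With p53 targets the correlation was 0.032 and 0.022.

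To ask which other transcripts accompany inflammatory expression, the 25% of cells with the highest inflammatory score were compared with the 25% with the lowest within each library (1300 against 1300 cells in replicate 1, 915 against 915 in replicate 2). In high-scoring cells 14 of 16 NF-kB genes were higher, and 32 of 32 mitosis, 13 of 14 contractile and 20 of 23 collagen genes were lower, while none of these lists passed with an estimated correlation (p = 0.213, 0.0781, 0.177 and 0.364). The strongest rise was that of IL23A, which encodes a subunit of interleukin-23. Its log2 fold change was 7.12 (SE 0.10, adjusted p = 1.15e-18 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). IL23A stood at only 1.05 and 1.02 CPM in the low-scoring cells of replicates 1 and 2. This SE, derived from the test statistic, therefore understates the counting error. The granulocyte growth factor CSF3 rose by 4.37 (SE 0.11), the adaptor gene PAG1 by 3.02 (SE 0.10), the matrix protease MMP3 by 2.94 (SE 0.08) and the cytokine IL24 by 2.89 (SE 0.10). Next came GJB2 (2.88), IL1RL1 (2.87), the decoy receptor gene IL13RA2 (2.73), C15orf48 (2.72) and STX11 (2.65). The largest declines were those of CDC20 (-3.88), MKI67 (-3.50), TOP2A (-3.36), ASPM (-3.34), TPX2 (-3.23), PRC1 (-3.07), the phospholipid-binding ANXA1 (-3.05), CENPF (-3.05), CCNB1 (-2.90) and the smooth muscle actin gene ACTG2 (-2.89).

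Of 16 NF-kB genes tested, 14 rose, VCAM1 fell (-0.74) and BCL3 did not pass (log2 fold change -0.0012), with a median of 1.14 (p = 0.213 for the list with an estimated correlation). PTGS2 (2.54), TNFAIP6 (2.08), IER3 (1.64) and NFKB1 (1.45) rose most. Of 29 SASP genes 20 rose and 7 fell, with a median of 0.69 (p = 0.0795 with an estimated correlation): MMP3, MMP10 (2.23), FGF2 (2.14) and SERPINB2 (2.00) rose, while IGFBP6 (-1.503) and IGFBP4 (-1.13) fell. Immediate early genes rose in 11 cases of 20 and fell in 3, with a median of 0.25 (p = 0.179 with an estimated correlation). In these 3 lists the counts adjusted over the list alone were the same.

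All 32 mitosis genes fell in high-scoring cells, with a median of -3.07 (p = 0.0781 for the list with an estimated correlation), and so did 19 of 25 DNA replication genes, with TK1 (-3.40) and RRM2 (-2.80) among them, while 2 rose (p = 0.167). Contractile genes fell in 13 of 14 cases, with a median of -1.13 (p = 0.177 with an estimated correlation), among them MYL9 (-2.10) and TAGLN (-2.02). Of 23 collagen and matrix genes 20 fell, and 21 when adjusted over the list alone, with a median of -0.70 (p = 0.364 with an estimated correlation): COL1A1 fell by 2.03 on the log2 scale and COL1A2 by 1.30. Interferon-stimulated genes fell in 19 of 26 cases and rose in 3 (median -0.90, p = 0.343 with an estimated correlation), with IFIT1 (-2.02) and XAF1 (-1.78) down and the transcription factor genes IRF1 (0.72) and IRF7 (0.72) up. Genes of the mixed arrest and quiescence list (6 rose, 15 fell, p = 0.188), complement genes (2 rose, 8 fell, p = 0.532) and hypoxia genes (2 rose, 14 fell, p = 0.456), each with an estimated correlation, were lower on balance. No direction was called for antigen presentation (3 rose, 2 fell), cholesterol synthesis (8 and 6), lysosome (5 and 8), mitochondrially encoded (2 and 0), p53 target (7 and 6) and YAP target genes (4 and 5). Adjusted over the list alone, 1 contractile gene rose, 2 antigen presentation genes rose, and the other counts of these lists were the same.

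Over all genes, 8579 of 14839 tested passed, 4265 higher and 4314 lower, and DESeq2 called 5031. Scores of random lists also called many genes: 20 random lists of matched expression gave 233 to 8283 genes (median 3317), and their highest medians were 0.37 for NF-kB and 0.24 for SASP genes. Medians as far from 0 as that of the inflammatory contrast arose in 1 of these 20 for contractile and collagen genes and in 0 for mitosis, NF-kB, SASP, interferon-stimulated and arrest genes. In deep barcodes, where both classes had similar depth, they arose in 5 of 20 for collagen and complement, 4 for contractile, 3 for DNA replication and hypoxia, 6 for immediate early, 1 for interferon-stimulated and 0 for mitosis, NF-kB, SASP and arrest genes, and 1 of 20 random lists gave as many genes as the inflammatory score. For mitosis genes the random medians came close. They ran from -1.92 to 2.85 in the main cells, against -3.07 with the inflammatory score. In deep barcodes they ran from -3.04 to 2.35, against -3.72. Large shifts of mitosis genes were thus not particular to the inflammatory score. High-scoring cells were deeper (median 26634.5 against 13322 UMIs in replicate 1, 35862 against 9469 in replicate 2). Without TMM scaling the median of all genes moved to -0.12, and 36.0% of 8261 calls were higher, against 49.7% with it.

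**Figure D3:**
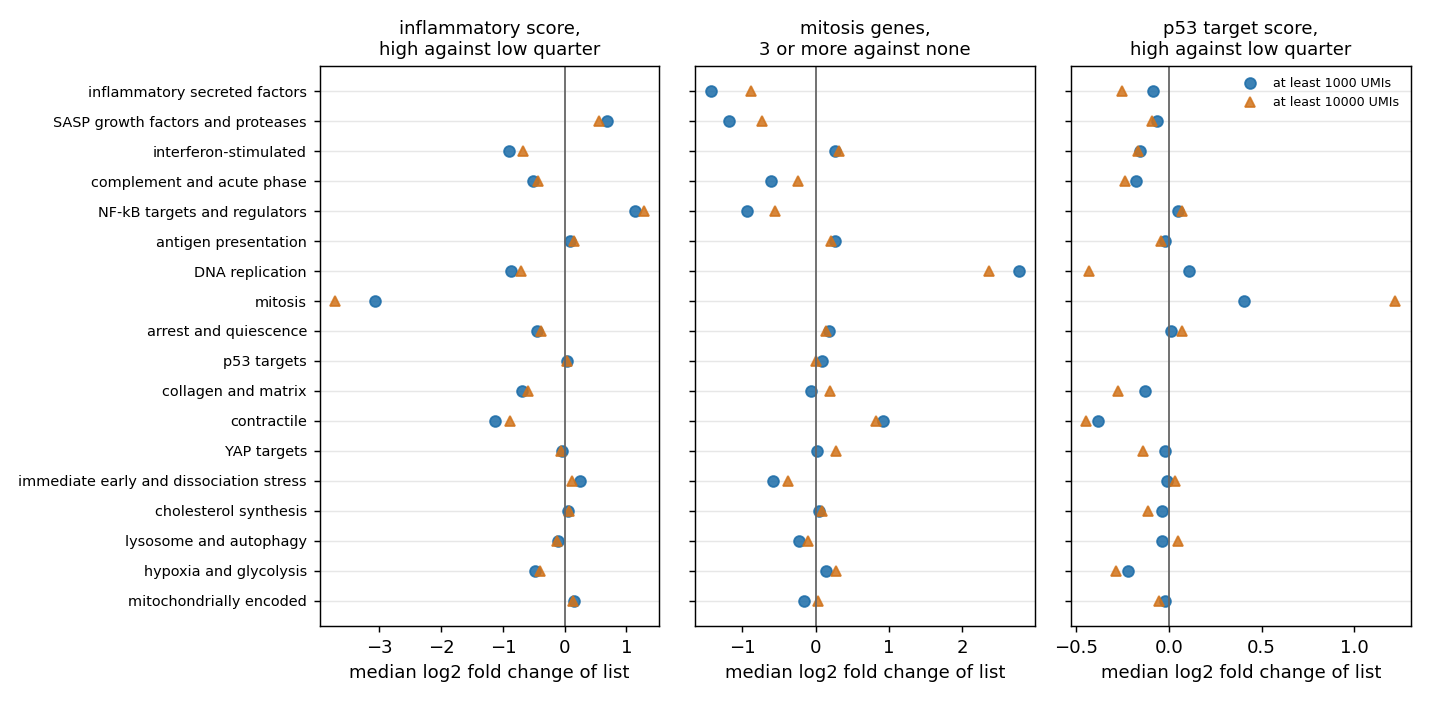
Median log2 fold change of each gene list in the 3 contrasts between cells, for cells with at least 1000 UMIs (circles) and deep barcodes with at least 10000 UMIs (triangles); the horizontal scales differ between panels, and the list that defines a contrast is not drawn in it. NF-kB genes lie highest and mitosis genes lowest with the inflammatory score (medians 1.14 and -3.07), and inflammatory genes lie lowest in cells with mitosis transcripts (-1.43).

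Cells with mitosis transcripts carried fewer inflammatory transcripts than cells without. The 132 and 104 cells with UMIs from 3 or more mitosis genes were compared with the 4504 and 3238 cells with none. Of 26 inflammatory factors tested 20 fell, and 21 when adjusted over the list alone, 1 rose and 5 did not pass, with a median log2 fold change of -1.43 (p = 0.0870 for the list with an estimated correlation). IL6 fell by 3.05 on the log2 scale (SE 0.13, adjusted p = 4.10e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the chemokine CCL20 fell by 4.21 (SE 0.17), CXCL5 fell by 2.34 (SE 0.10) and CXCL8 fell by 1.53 (SE 0.14). IL33 had 919 UMIs in cells without and 0 in cells with mitosis transcripts, where 26.9 would be expected from depth. Few barcodes held its UMIs (2.04% and 2.40% of deep barcodes had one). A count of 0 in 132 and 104 cells can thus come from which cells were drawn, and no fold is given. CXCL12, a stromal chemokine, rose (1.04, SE 0.22), and CSF2 did not pass (0.035, SE 0.10).

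Outside the list the largest declines were those of IL23A (-5.87), the glycoprotein hormone subunit CGA (-4.75), MMP3 (-4.41), CHI3L1 (-3.16), the cortisol-producing enzyme gene HSD11B1 (-3.05), IL24 (-2.98), CCL11 (-2.91) and the cytokine signal inhibitor SOCS3 (-2.91). In deep barcodes IL23A was at -5.51, while the others shrank to -1.59 (CGA), -1.75 (MMP3), -1.95 (CHI3L1), -1.91 (HSD11B1), -1.39 (IL24), -0.53 (CCL11) and -1.23 (SOCS3). SASP genes fell in 21 of 29 cases and rose in 2 (median -1.19, p = 0.0922 with an estimated correlation). NF-kB genes fell in 13 of 16 cases and rose in 2 (median -0.94, p = 0.324 with an estimated correlation), with PTGS2 (-2.33) and TNFAIP6 (-2.23) down and BIRC3 (1.23) up. VCAM1 also fell (-2.58) but was higher in deep barcodes (0.35), where the medians of SASP, NF-kB and immediate early genes were -0.74, -0.56 and -0.38. Immediate early genes fell in 15 of 20 cases and rose in 3 (median -0.59, p = 0.250 with an estimated correlation). Contractile genes rose in 13 of 14 cases (median 0.92, p = 0.288 with an estimated correlation), among them ACTG2 (1.80), CNN1 (1.61) and TAGLN (1.30).

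Genes of the cell cycle itself rose by construction and are not a finding, among them NEK2 (10.15), DEPDC1 (9.45), KIF2C (9.33), CEP55 (9.15), SPC25 (8.97), CDCA8 (8.88), NUF2 (8.85), PIMREG (8.83), KIF20A (8.79) and CDC25C (8.68). DNA replication genes rose in 22 of 25 cases (median 2.78, p = 0.0885 with an estimated correlation), and LMNB1 rose by 4.77 (SE 0.17). In the arrest and quiescence list, which includes LMNB1 and CCND1, 11 of 24 genes rose and 6 fell (p = 0.319 with an estimated correlation). This mixed list is not read as a change of arrest. Interferon-stimulated genes rose in 8 of 29 cases and fell in 3 (p = 0.265 with an estimated correlation). Mitochondrially encoded genes fell in 4 of 13 cases (p = 0.620 with an estimated correlation), with a median of -0.16 that was 0.03 in deep barcodes. Counts of genes that rose and fell were 5 and 2 of 13 for antigen presentation, 5 and 3 of 19 for cholesterol synthesis, 3 and 8 of 23 for collagen, 2 and 6 of 12 for complement, 8 and 5 of 17 for hypoxia, 1 and 7 of 18 for lysosome, 6 and 2 of 21 for p53 targets and 5 and 2 of 16 for YAP targets, with no call for any of these lists in cells with at least 1000 UMIs. Some of these differed in deep barcodes, where the rule for the class differed as well. There collagen genes rose in 13 cases and fell in 8 (median 0.19, against -0.063). YAP targets rose in 9 and fell in 0 and were called higher (p = 0.238 with an estimated correlation). Adjusted over the list alone, 22 SASP, 14 NF-kB, 7 arrest, 5 mitochondrially encoded, 1 DNA replication and 6 hypoxia genes fell, 6 cholesterol synthesis and 3 complement genes rose, and the other counts were the same.

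In all, 4929 of 15890 genes passed, 2443 higher and 2486 lower, and DESeq2 called 3021. The cells with mitosis transcripts were shallower (median 3391 against 20812.5 UMIs in replicate 1, 3684.5 against 30265 in replicate 2). In deep barcodes, where they were the deeper class (46070 against 39758 UMIs in replicate 1, 57827 against 46051.5 in replicate 2), 19 of 26 inflammatory factors fell, the median was -0.88, IL6 fell by 1.42 and CCL20 fell by 1.63 on the log2 scale. Without TMM scaling the median of all genes moved from -0.079 to 0.12, and 71.8% of 5083 calls were higher, against 49.6% with it.

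Whether inflammatory expression accompanies the p53 checkpoint program, which is shared with senescence, was asked with the same design scored on p53 targets. Of 26 inflammatory factors 22 did not pass, 4 were lower and 0 were higher in the cells with high p53 target expression. The damage recognition gene DDB2, itself a known p53 target outside the list, rose by 1.59 on the log2 scale, the thymidylate synthase gene TYMS by 0.93 (SE 0.06) and PCNA by 0.86 (SE 0.06). STOM (0.92), ASCC3 (0.86), PAPPA (0.76), FBXO22 (0.70) and the glycolysis regulator gene TIGAR (0.63) were higher as well. The actin gene ACTG2 fell by 1.15 (SE 0.06, adjusted p = 0.000391 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), TAGLN by 1.03 (SE 0.04) and MYL9 by 0.92 (SE 0.06). Also lower were ISG20 (-0.77), NDUFA4L2 (-0.67), ANXA1 (-0.66), ACTB (-0.59), ANXA2 (-0.59), THY1 (-0.57) and CD9 (-0.57, but 0.014 with a mitochondrial limit of 5%). CENPF (0.57) and ACTA2 (0.56) were also higher, but CENPF, ACTA2 and TIGAR turned to -1.23, -0.0043 and -0.024 in sums of thinned UMIs. Deep barcodes gave larger changes for DDB2 (3.21), TYMS (1.44), STOM (1.77), ACTA2 (1.41) and CENPF (1.45), and there ANXA1 (-0.31) did not pass.

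Adjusted over the list alone, 7 inflammatory factors fell and 1 rose, and the median of the list was -0.087 (p = 0.131 with an estimated correlation). Without TMM scaling the list was at 0.0032, but the median of all genes then moved from 0.0048 to 0.0958, so the list stayed below it. In deep barcodes 13 inflammatory factors fell, 2 rose and 11 did not pass, with a median of -0.25 (p = 0.112 with an estimated correlation). The 4 that passed over all genes were CXCL12 (-0.87), IL1B (-0.43), CCL2 (-0.26) and IL33 (-1.74, but 0.15 with a mitochondrial limit of 5%, and not passing in deep barcodes). Contractile genes fell in 8 of 14 cases and rose in 1 (p = 0.0519 with an estimated correlation), hypoxia genes fell in 8 of 17 (p = 0.175) and complement genes in 3 of 12 (p = 0.115). Their medians were -0.39, -0.22 and -0.18. The 20 random scores, matched to the inflammatory list, gave medians from -0.87 to 1.30, -0.45 to 0.59 and -0.44 to 0.63 for these lists. Shifts of this size were thus not particular to the p53 score. SASP genes fell in 6 of 29 cases and rose in 1, GDF15 at 0.50 (p = 0.147 with an estimated correlation). Mitosis genes rose in 3 of 32 cases (p = 0.397 with an estimated correlation) and DNA replication genes in 2 of 25, TYMS and PCNA (p = 0.310). These directions were not stable: in deep barcodes 32 of 32 mitosis genes rose with a median of 1.22, but the mitosis median of 0.41 in the main cells was -0.21 with 10000 to 80000 UMIs, -0.31 with sums of thinned UMIs and -0.049 without replicate 1. Of 25 DNA replication genes 11 fell and 2 rose in deep barcodes. Interferon-stimulated genes fell in 3 of 26 cases (p = 0.176 with an estimated correlation), collagen genes in 1 of 23 (p = 0.513) and YAP targets in 1 of 15 (p = 0.432). In deep barcodes more genes fell: 15 of 23 collagen (median -0.27), 13 of 17 hypoxia, 12 of 29 SASP and 6 of 15 YAP target genes. The NF-kB list was called higher with 0 of 16 genes passing (p = 0.346 with an estimated correlation). Arrest genes (1 rose), immediate early genes (1 rose, 1 fell) and antigen presentation, cholesterol synthesis, lysosome and mitochondrially encoded genes (0 passed) were not called. Adjusted over the list alone the genes that rose and fell were 1 and 11 for contractile, 0 and 11 for hypoxia, 0 and 7 for complement, 4 and 11 for SASP, 8 and 0 for mitosis, 4 and 1 for DNA replication, 1 and 8 for interferon-stimulated, 2 and 9 for collagen, 0 and 3 for YAP target, 5 and 1 for NF-kB, 3 and 7 for arrest and 1 and 0 for cholesterol synthesis genes, with the other lists the same.

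In all, 343 of 14610 genes passed, 103 higher and 240 lower, with 2736 at an unadjusted p under 0.05, and 19 of the 20 random lists gave as many. Without the replicate block 14 genes passed. In deep barcodes 2369 did, and 15 of 20 random lists gave as many there. Without TMM scaling 86.4% of 1717 calls were higher, against 30.03% with it.

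Unsupervised clustering gave 8 clusters, 4 of which (4 to 7) were shallow, with medians between 1314 and 3924 UMIs in the 2 replicates, and stay unnamed. Shallow cluster 7 held 10.1% and 11.8% of cells and had TK1, TAGLN, RRM2, BIRC5 and PCLAF among its leading genes. Of the 8 clusters it had the lowest CXCL8 (2426 CPM) and IL6 (374 CPM) and the highest TAGLN (3663 CPM). Only cluster 8 earned a name from the markers, as cycling-like, with ASPM, MKI67, TOP2A, UBE2C and CENPF among its leading genes. It held 1.02% and 1.34% of cells (1.18 ± 0.23%, SD, n = 2), which were 53 and 49 cells at medians of 53203 and 79359 UMIs. No cluster of that size and depth was found at the resolutions 0.3 and 1.0. The 132 and 104 cells with mitosis transcripts had medians of 3391 and 3684.5 UMIs, so cluster 8 cannot hold all of them. In the deep barcodes 5 clusters were found. Cluster 1, led by ADAMTS8, VCAM1 and LXN, held 25.8 ± 1.33% of barcodes, cluster 2, led by IL23A, PAG1 and IL24, 34.4 ± 0.81%, cluster 3, led by IL7R, IL1B and MT1G, 15.3 ± 0.91%, cluster 4, led by PGF, SPOCK1 and LINC01436, 18.9 ± 2.18%, and the cycling-like cluster 5 held 5.57 ± 0.86% (SD, n = 2). Leading genes name a cluster and are not results of a test.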

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

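Of the tests in this part, those on free RNA and CXCL8 were chosen after the result was seen, and those on mitosis transcripts in shallow barcodes were written before. No biological explanation was tested, since the design has 1 group.

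Barcodes under 1000 UMIs enter no comparison between cells, and CXCL8 was at 10429.67 CPM in those of replicate 1 and 12035.44 CPM in those of replicate 2. They are listed because 99.8% of them had a CXCL8 UMI, where a count of 0 would allow at most 0.133% and 0.118%, which shows only that CXCL8 is present in them. A test of whether free RNA brings the CXCL8 transcripts of deep barcodes decided nothing: the median count of shallow barcodes was 3.0% and 1.61% of that of deep ones, but for all UMIs the same ratio was 2.2% and 1.4%. That a varying amount of free RNA sets the CXCL8 differences between deep barcodes is argued against by the 27.0% and 31.88% of them with CXCL8 above 1.5 times the level of shallow barcodes. In the 10% of deep barcodes with the lowest CXCL8 it was at most 418.1 and 403.0 CPM. Free RNA with the CXCL8 level of shallow barcodes can thus make up only a small part of the UMIs in those barcodes. For the other deep barcodes this gives no limit. How much of the CXCL8 in deep barcodes comes from free RNA, and which shallow barcodes are empty droplets or remnants of cells, stays open.

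UMIs from 3 or more mitosis genes were present in 1.111% and 1.846% of barcodes under 1000 UMIs, listed for the same reason, which shows only that such barcodes exist. Free RNA of 1 composition is argued against, since barcodes of 1000 to 2000 UMIs carried such transcripts 4.21 and 3.96 times as often as the pooled profile gives. Damaged whole cells, which keep mitochondria while losing cytoplasm, are argued against by the median mitochondrial share of these barcodes, 0.763% and 0.557%. The low share is not particular to barcodes with mitosis transcripts, since all barcodes of 1000 to 2000 UMIs had medians of 0.811% and 0.814%. Remnants of dividing cells without mitochondria, and free RNA whose composition differs between droplets, stay open.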

How the results depend on the processing

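The settings with deep barcodes (at least 10000 UMIs), with 10000 to 80000 UMIs, and their combinations, were chosen after the depth of the barcodes was seen; of the tests below, the other settings were planned. For each change the cause was not tested, except where a setting changes the depth at which UMIs are counted.

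The share of cells with mitosis transcripts (2.69%) was 4.062% with 2 or more genes, 1.548% with 5 or more, 15.228% not thinned, 6.389% in deep barcodes, 21.356% in deep barcodes not thinned and 5.346% with 10000 to 80000 UMIs; counting at greater depth shows more genes. The spread of inflammatory genes (-0.40) was -0.3927 with thinned counts, -0.3947 with all barcodes, -0.403 to -0.394 with 1 replicate left out, -0.3109 in deep barcodes, -0.3154 in deep barcodes thinned and -0.3273 with 10000 to 80000 UMIs. Their co-variation (0.080) was 0.1269 on the log scale, where random lists also rose to 0.0601 and 0.0676 in the 2 libraries (from 0.0018 and 0.0016) and DNA replication and YAP target genes lay at percentiles 95.37 and 96.31 in replicate 1, 0.0599 in deep barcodes, 0.0733 in deep barcodes on the log scale and 0.0597 with 10000 to 80000 UMIs. Deep barcodes gave 5 clusters in place of 8.

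Genes passing in the inflammatory contrast (8579) were 2142 with sums of thinned UMIs, 5031 with DESeq2, and in deep barcodes 5308 without the replicate block and 3867 with DESeq2. In the mitosis contrast (4929) they were 3038 with 10000 to 80000 UMIs, 783 with sums of thinned UMIs, 3021 with DESeq2, and in deep barcodes 3264 without the block and 2582 with DESeq2. In the p53 contrast (343) they were 560 with all barcodes deep enough, 761 with the 5% mitochondrial limit, 1936 with 10000 to 80000 UMIs, 803 with a sum score, 1717 without TMM, 833 without the low-count filter and 14 without the block. In deep barcodes the p53 contrast gave 2369, with thinned sums 1141, without TMM 3724, without the filter 2627, without the block 58 and with DESeq2 571.

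Medians of lists without a call in the 1000-UMI cells are not compared here. Among the lists with a call in the inflammatory contrast, the median of immediate early genes changed sign, to -0.0271 in deep barcodes without TMM. There the median of all genes was -0.1437, and with TMM the list was at 0.1176. The change of sign thus follows the shift of all genes and is no reversal of the list. In the p53 contrast the DNA replication median (0.11) reversed to -0.2615 with all barcodes, -0.2509 with the 5% limit, -0.2262 with 10000 to 80000 UMIs, -0.0707 with thinned sums and -0.0826 with the top and bottom 10%. In deep barcodes it was -0.4329, with thinned sums -0.2506, without TMM -0.3049, without the filter -0.4364, without the block -0.4344 and with DESeq2 -0.4397. The NF-kB median (0.049) turned to -0.0056 with the 5% limit, -0.0004 with 10000 to 80000 UMIs and -0.0145 with the top and bottom 10%. The mitosis median (0.41) turned to -0.2079 with 10000 to 80000 UMIs, -0.3135 with thinned sums -0.0493 without replicate 1 and 0.7275 without replicate 2. Without TMM the p53 medians of SASP (0.0283, deep 0.0353), YAP target (0.0664) and inflammatory genes (0.0032) turned positive. The median of all genes was then 0.0958 (deep 0.1347), so these lists stayed below it, and the change of sign is no reversal of the lists. In the mitosis contrast the interferon-stimulated median (0.26) turned to -0.1918 with thinned sums. The mitochondrially encoded median (-0.16) turned to 0.0306 with 10000 to 80000 UMIs and 0.049 without TMM, where the median of all genes was 0.125. In deep barcodes it was 0.0298, with thinned sums 0.0155, without TMM 0.2134, without the filter 0.0079, without the block 0.0325 and with DESeq2 0.0293.

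Single genes of the p53 contrast that reversed were ACTA2 (-0.0043), CD9 (0.077), CENPF (-1.23) and TIGAR (-0.024) with thinned sums, CD9 (0.014), CLU (0.10) and IL33 (0.15) with the 5% limit, and SERPING1 (0.020) in deep barcodes without TMM, where the median of all genes was 0.1347. In the mitosis contrast ADM turned to 0.043 with 10000 to 80000 UMIs, 0.11 in deep thinned sums and 0.039 in deep barcodes without TMM. With thinned sums CTSK turned to -1.04, EGR3 to 0.69, HK2 to 0.039 and STARD4 to -0.67, and in deep thinned sums DES turned to 0.11. MT-ND1 turned to 0.031 with 10000 to 80000 UMIs, 0.0088 in deep thinned sums and 0.15 in deep barcodes without TMM, where MT-CO1 (0.10), MT-ND3 (0.064) and TP53I3 (0.13) turned too. In that last setting the median of all genes was 0.1719, above the values of these genes and of ADM. VCAM1 (-2.58) was 0.35 in deep barcodes, 0.59 with deep thinned sums, and in deep barcodes 0.52 without TMM, 0.33 without the filter, 0.34 without the block and 0.34 with DESeq2. Over the planned settings other than leaving a replicate out, 709 of 727 gene values of the inflammatory contrast, 299 of 386 of the p53 contrast and 679 of 739 of the mitosis contrast kept their direction and their side of the adjusted p of 0.05, whatever their size. Over the added settings 554 of 572, 264 of 315 and 457 of 585 did. In the mitosis contrast 16 values reversed in the added settings, against 4 in the planned ones. Leaving a replicate out moved by more than the SD between the libraries 59 of 166, 10 of 90 and 56 of 168 gene values of these contrasts. Apart from that rule, CCL11 in the mitosis contrast (-1.95 in replicate 1, -4.69 in replicate 2) and IL1RL1 in the inflammatory contrast (2.03 and 3.32) differed between the libraries. The planned setting without Scrublet calls was not run.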

Other observations

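The tests on lower inflammatory transcripts in cells with mitosis transcripts were chosen after the result was seen. No biological explanation was tested.

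Beyond the inflammatory genes, the scores of deep barcodes formed a second set that moved together. Complement and collagen scores correlated at r = 0.59 and 0.60 (replicates 1 and 2), collagen with contractile at 0.53 and 0.51, collagen with hypoxia at 0.52 and 0.55, and interferon-stimulated with contractile at 0.40 and 0.37. The inflammatory score ran against each of these in deep barcodes, at -0.35 and -0.26 for collagen, -0.33 and -0.32 for contractile, -0.35 and -0.33 for hypoxia, -0.29 and -0.24 for interferon-stimulated and -0.25 and -0.19 for complement genes. Within the inflammatory list IL11 ran against CXCL12 (mean r = -0.13) and IL6 against TNFRSF11B (-0.13).

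MALAT1, a nuclear RNA, was highest in barcodes of middle depth. It was at 47115 and 38413 CPM in barcodes of 2000 to 5000 UMIs, 82842 and 68921 at 5000 to 10000 UMIs, 45586 and 35323 at 10000 to 20000 UMIs, and 21384 and 18263 at 20000 to 50000 UMIs. The median mitochondrial share in these ranges was 1.27% and 1.15%, 7.47% and 5.86%, 3.43% and 2.99%, and 2.51% and 2.27%. The range of 5000 to 10000 UMIs held 461 and 294 barcodes, and the cause was not tested.

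Inflammatory factors were lower in cells with mitosis transcripts, with a median log2 fold change of -1.43. Shallow barcodes in that class as the cause are argued against by the deep barcodes, where the median was -0.8816. With a mitochondrial limit of 5% the median was -1.177, which argues only against cells above that limit as the cause. The limit took the class without mitosis transcripts from 4504 to 4220 and from 3238 to 3036 cells. So small a loss cannot decide whether that class holds more damaged cells. The median of all genes outside the mitosis list in deep barcodes without TMM scaling was 0.1719. It could not decide whether mitosis transcripts take a share of the total and so lower all other genes. Their list summed to only 331 and 379 CPM over the deep barcodes of replicates 1 and 2, which could hardly move that median. The size of the difference stays open, since it changed with depth. As a hypothesis, cells that escape arrest could express fewer inflammatory factors, which the value of -0.8816 in deep barcodes does not rule out; sequencing of sorted cells would be needed.

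What the libraries cannot show is whether quiescence raised inflammatory transcripts, since proliferating and senescent cells are not analysed here. The contact inhibition and the serum withdrawal cannot be separated, and the trypsin step may have added immediate early transcripts. Their median in the inflammatory contrast was 0.25, and 0.1176 in deep barcodes. Without TMM scaling it was -0.0271 in deep barcodes, where the median of all genes was -0.1437.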
